A study of Mus musculus with 2 samples.

How the data were processed

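Gene expression was measured on Affymetrix 3' arrays in 2 samples of mouse cells, per the labels' protocols. Both samples came from A2lox.Mesp1 embryonic stem cells, a line of the 129/Ola strain background in which doxycycline (dox) switches on a Mesp1 transgene. The cells were grown as embryoid bodies, aggregates in which stem cells differentiate, from 15000 cells/mL in medium with 10% fetal calf serum. One culture received no dox and the other was exposed to 250 ng/mL of dox between day 2 and day 4. On day 5 the cells that carried both Flk1 (the receptor encoded by Kdr) and Tie2 (the receptor encoded by Tek) on their surface were sorted by flow cytometry. Total RNA was purified on columns, and 100 ng of it was amplified into biotin-labelled RNA for each array.

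The deposited table holds 1 linear signal intensity per probe set and array, for 45037 probe sets on 2 arrays. The method by which the authors summarised and scaled these intensities is not given in the sources used here. In both columns the lowest intensity is exactly 1, reached by 1165 probe sets without dox and 1102 with dox, so very dim values had been set to a floor. The median intensity was 112 without dox and 127 with dox, and the highest was 22018 and 22539. The table used here carries no control probe sets, detection calls or probe-level values. Background, saturation and RNA quality could therefore not be judged from spike-in or 3'/5' probes, and no dim value could be marked as undetected. Scanner files were not used here. The number of arrays, 1 per condition, limits the precision of every value.

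Probe sets were named through the array's platform annotation. Of the 45037 probe sets, 34945 had 1 gene symbol, 932 had several and were left unnamed, and 9160 had no gene listed and were not analysed as genes. The Entrez gene number of 34741 named probe sets was found in the RefSeq gene table of assembly GRCm38.p6, which changed no symbol, and the array's own symbol was kept for the other 204. No genome build is named for the array values, so no coordinates are given.

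Signals were analysed as log2(signal + 16), a pseudocount that damps the noise of dim probe sets and understates the change of dim genes. Every log2 difference is dox minus no dox on that scale, and every fold is 2 to the power of that difference. Each gene was represented by its brightest probe set, by the mean of both arrays. A gene was analysed further when the brighter of its 2 signals reached the median of its array (the signal filter), which left 11794 of 18193 genes. These choices were written down before the data were examined, as were the gene lists, the fold threshold and the alternatives. Where the files could have held log2 values a different scale had been foreseen, and the pseudocount was used because the values were linear.

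With 1 array per condition there is no replicate error, no test between the conditions and no p-value. Genes were therefore described by a fixed size, an absolute log2 difference of 1 or more (2-fold). The only error within these arrays is the disagreement between probe sets of the same gene. Its pooled SD was 0.38 log2 units over 13823 probe sets of 5173 genes. It came to 0.48 for probe sets with a mean signal under 500 and 0.26 for brighter ones. That SD measures probe effects and noise, not the variation between cultures or arrays.

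A total of 23 gene lists with 466 entries was fixed from general knowledge of the tissue, the sort and the treatment, and 441 entries had a named probe set. The lists covered hematopoietic transcription factors, erythroid genes, progenitor, megakaryocyte and myeloid genes, endothelial, arterial, venous and endocardial genes, cardiac factors and cardiomyocyte genes, skeletal, smooth muscle and mesenchyme genes, regulators of epithelial-mesenchymal transition, streak, pluripotency, endoderm and neural genes, the cell cycle, the BMP and Wnt pathways, Hox genes, stress and immediate early genes, and housekeeping genes. For each list with at least 5 genes past the filter, the median log2 difference was set against the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. The place of a list among its random lists describes these 2 arrays and does not extend to other cultures. The random lists treat genes as independent, which genes of one pathway are not.

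The genes named in the text follow a rule. They are Mesp1 and the genes of the sort (Kdr and Tek), and up to 12 hematopoietic transcription factors that differed 2-fold or more. The 3 members of each other list with the largest absolute difference were also named. The last part holds the 10 genes with the largest positive and the 10 with the largest negative difference whose probe sets past the filter all differed in the same direction. Any other gene named in the text was chosen after its values were seen.

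The procedure was tested on simulated data before use. In a simulated pair made from the mean real signals with noise of 0.25 log2 units per array, 11659 genes passed the filter. All 100 genes changed 4-fold and all 100 genes changed 8-fold were called in the right direction (100% each), and 0.568% of 11448 unchanged genes passed 2-fold. The noise was assumed and the same at every signal, while the probe set SD was 0.48 for dim and 0.26 for brighter probe sets. The simulation therefore checks the procedure and does not estimate false calls in the real arrays, whose noise is unknown. A list shifted by 1.5 log2 units had a recovered median of 1.56, and 1 of 20 other lists fell outside the central 95% of its random lists.

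The 9 alternatives changed 1 choice each. They were quantile normalization of the arrays, centring on a loess curve (span 0.3), no signal filter, a filter at the 75th percentile, a filter on both arrays, the mean of a gene's probe sets in place of the brightest, removal of probe sets whose names end in _x_at or _s_at (which can cross-hybridise), and pseudocounts of 1 and 64. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.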

Results

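Flk1+Tie2+ cells, a fraction that contains the endothelium of embryoid bodies, were profiled on day 5 of differentiation with and without a pulse of Mesp1. Mesp1 is a transcription factor of early mesoderm that takes part in forming the cardiovascular lineages. The data consist of 1 array without dox and 1 array of cells exposed to 250 ng/mL of dox between day 2 and day 4. The comparison addresses which genes, and in particular which transcription factors linked to blood formation, differ in this endothelium after Mesp1 induction. With 1 array per condition, every difference below compares these 2 samples, has no replicate check and carries no p-value. Signals are in the arbitrary units of the deposited table.

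Mesp1 itself was higher with dox. Its only probe set gave a signal of 2433 without dox and 10977 with dox, a 4.49-fold difference (log2 difference 2.17) on the log2(signal + 16) scale. Whether that probe set detects the transgene, the endogenous transcript or both could not be checked without probe sequences, so the difference may not measure the transgene. The labels place the end of dox at day 4, before the sort on day 5. The genes of the sort differed little. Kdr, which encodes Flk1, had signals of 10139.7 and 10733, and Tek, which encodes Tie2, had signals of 8799 and 9277, a log2 difference of 0.08 for each. Housekeeping genes had a median log2 difference of 0.01, and all 12 measured members stayed within 2-fold. Among them Gusb differed by 0.61, B2m by 0.43 and Polr2a by 0.38, although the probe sets of Polr2a went in both directions.

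Of 11794 genes past the signal filter, 671 were 2-fold or more higher with dox and 243 were 2-fold or more lower, while 92.3% lay within 2-fold. At 4-fold the counts were 237 higher and 25 lower, and at 8-fold they were 88 and 3. These counts depended on the processing. With a filter on both arrays they were 110 and 7 at 4-fold and 26 and 0 at 8-fold, and with a pseudocount of 1 they were 261 and 34 at 4-fold and 113 and 10 at 8-fold. The signals of all probe sets correlated between the arrays with Pearson's r of 0.974 on the log2 scale, a correlation across probe sets, which are not independent replicates. The share of higher genes among those past 2-fold was 73.4% (Wilson 95% interval 70.5 to 76.2, for counting error only). After quantile normalization the counts were 589 higher and 320 lower, and this share was 64.8%.

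**Figure D1:**
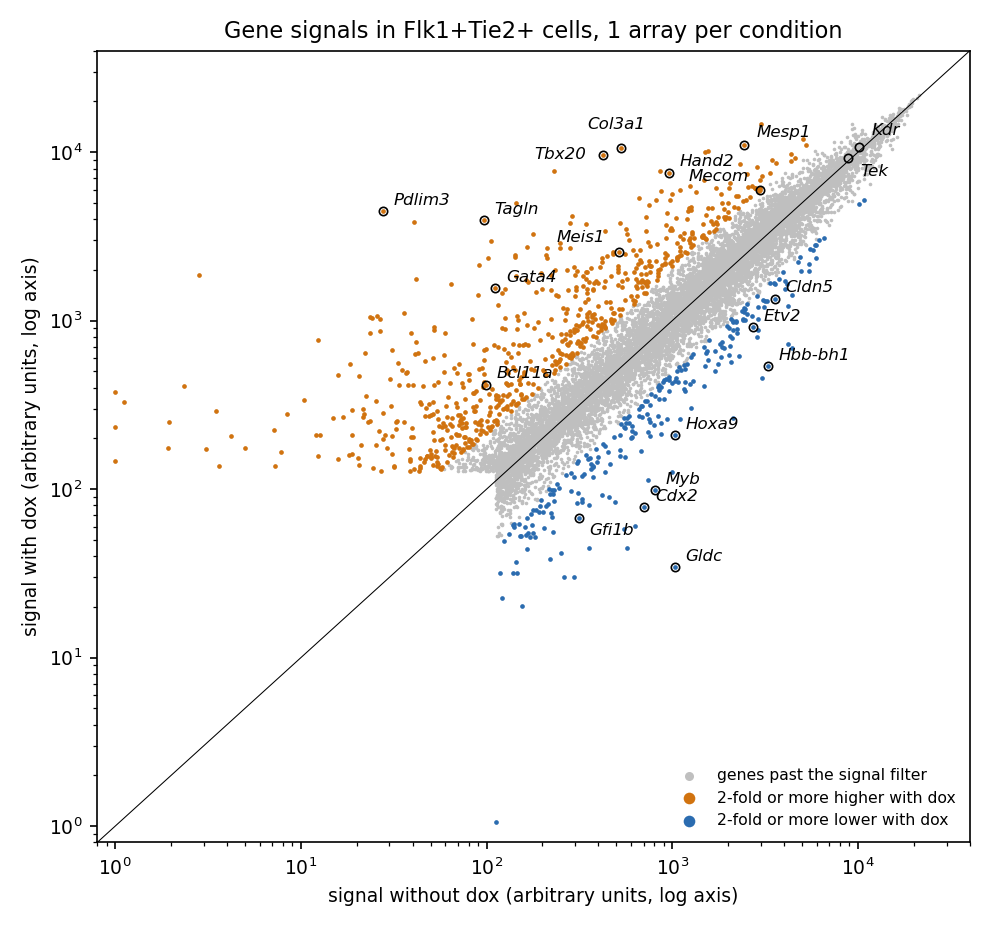
Signal of each gene's brightest probe set without dox (x) and with dox (y), both on log axes in arbitrary units, for 11794 genes past the signal filter, with 1 array per condition. Orange points (671) were 2-fold or more higher with dox, blue points (243) were 2-fold or more lower, circled genes are named, and Kdr and Tek lie near the line of equal signal.

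Pdlim3, which encodes a muscle protein of the actin cytoskeleton, and Shisa3 had the largest positive differences, and which of them came first depended on the scaling and the pseudocount. Pdlim3 had a signal of 27.8 without dox and 4451 with dox, 102-fold higher. Shisa3 had 2.83 and 1874, although another of its probe sets differed by a log2 difference of only 1.66. Tagln (transgelin, an actin-binding protein of smooth muscle) was 35.3-fold higher, Tgfbi (a matrix protein induced by TGF-beta) 31.6-fold, and Col5a2 (a fibrillar collagen chain) 31.2-fold. Cryab (a small heat shock protein), Sox9 (a transcription factor of cartilage and heart valves), Mgat4c, Ccbe1 (required for lymphatic growth) and Gpr50 were between 25.8-fold and 30.9-fold higher. All but Tgfbi and Col5a2 of these 10 genes had a signal below the array's median of 112 without dox, so the size of their fold depends on the pseudocount. The same holds for every other gene given below with a signal under that median on its dimmer array, such as Lum, Hoxa2, Myl4 and Npr3.

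On the lower side Gldc, the glycine decarboxylase of the mitochondrial glycine cleavage system, had a signal of 1029 without dox and 34.6 with dox, 20.7-fold lower. Fgf3 was 9.63-fold lower, Zfp646 8.46-fold, and Cdx2, a caudal-type homeobox factor of posterior mesoderm, 7.71-fold. Tfec was 7.68-fold lower and Atp2a3, a calcium pump, 7.67-fold. Myb, a transcription factor of definitive blood progenitors, was 7.20-fold lower. Fermt3, an integrin-activating protein of blood cells, was 7.14-fold lower. Gjb5, a connexin, was 6.76-fold lower (295 to 30.05). Cldn23 was 7.56-fold lower (112.92 to 1.06), but it barely passed the signal filter and its signal with dox lay near the floor of 1. The other probe sets of Fgf3 gave log2 differences of -2.66 and -0.86. The other probe set of Zfp646 gave -0.04, so its difference rests on 1 probe set.

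Hematopoietic transcription factors, the group that the title of the series is about, differed in both directions. By the brightest probe sets of 29 measured members, 4 were 2-fold or more higher with dox, 5 were 2-fold or more lower and 20 lay within 2-fold. The higher genes were Meis1, a homeobox cofactor of blood stem cells (515 to 2543, 4.82-fold), and Bcl11a, a zinc finger factor that represses embryonic and fetal globins (99.3 to 417, 3.75-fold). The ETS factor Elf1 (342 to 789, 2.25-fold) and Mecom (2959 to 6003, 2.02-fold), which maintains blood stem cells, were the others. The lower genes besides Myb (809 to 98.6) were Hoxa9 (1034 to 209, 4.68-fold lower) and Gfi1b, a repressor needed for red cells and platelets (314 to 67.3, 3.96-fold lower). Etv2, an ETS factor needed to form blood and endothelium (2716 to 913), was 2.94-fold lower, and Nfe2, a factor of megakaryocytes (360 to 154), was 2.22-fold lower.

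Probe sets disagreed for some of these factors. The remaining probe set of Meis1 gave a log2 difference of -0.22 against 2.05 and 2.27 for the others. The probe sets of Bcl11a ranged from -0.22 to 3.16, and a dimmer probe set of Hoxa9 gave -0.02. Both probe sets of Myb past the filter were lower, with log2 differences of -2.85 and -2.94. Some factors central to early blood formation were looked up after their values were seen, and these lay within 2-fold by their brightest probe sets. Tal1 had a log2 difference of -0.44 (5712 to 4207), Gata1 -0.78 (273 to 153), Gata2 0.13 (4424 to 4855) and Runx1 0.21 (161 to 188). For Runx1, 5 further probe sets lay below the signal filter and disagreed. Lower with dox were those with signals of 84.9 to 27.1, 50.04 to 5.17 and 6.19 to 2.97. Higher were those with 35.07 to 44.85 and 7 to 7.81. Also named after their values were seen, Lyl1 (-0.93), Fli1 (-0.78), Lmo2 (-0.60) and Erg (-0.20) lay within 2-fold by their brightest probe sets. Other probe sets past the filter exceeded 2-fold, at -1.30 for Fli1, -1.81 for Erg and 1.06 for Hoxb4. The median log2 difference of the list was -0.29, below all 10000 random lists matched on signal, whose central 95% ran from -0.09 to 0.20. By any amount 17 members were lower and 12 higher. The 95% rank interval of the median, taken from the ordered values of the members, ran from -0.60 to 0.13 and so held no difference. The list's members were chosen from general knowledge, but its theme came from the series title, so it is not independent of the study. In the same sample the erythroid list had a median of -0.58 and the smooth muscle and mesenchyme list one of 2.11.

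**Figure D2:**
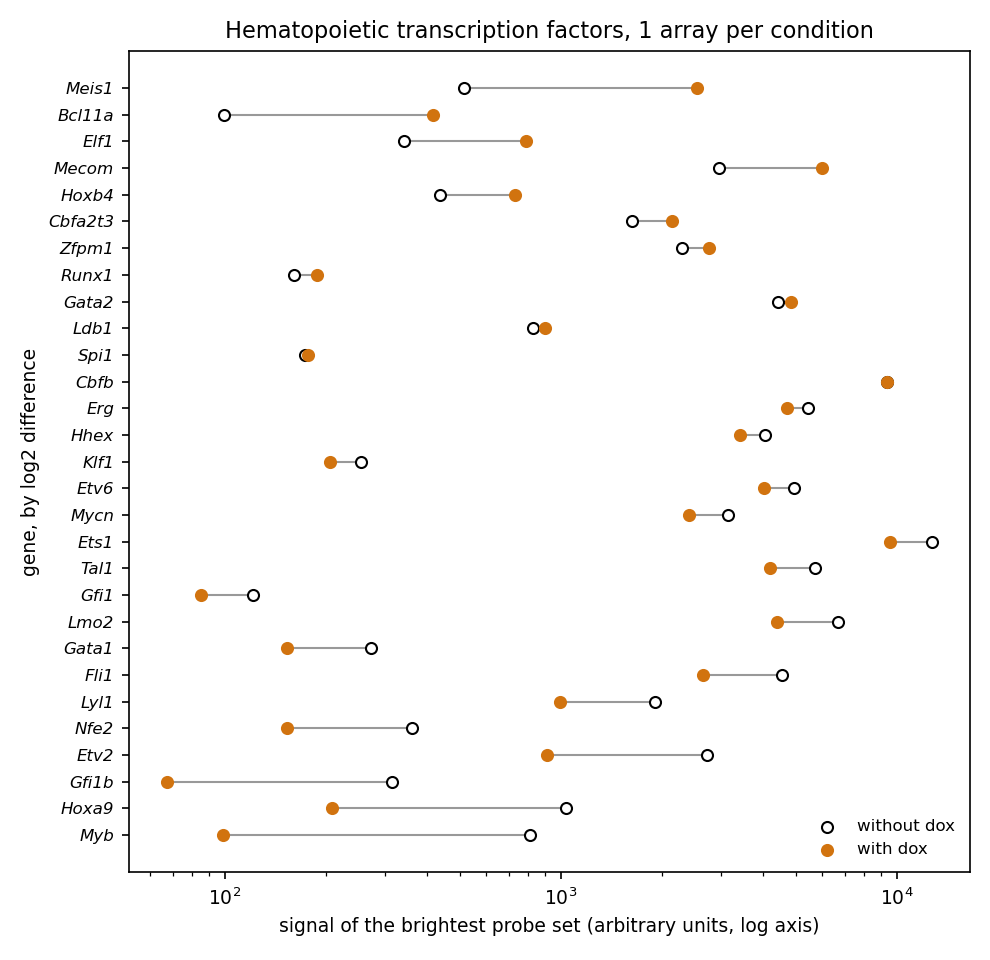
Signal of each measured hematopoietic transcription factor (29 genes past the filter, ordered by log2 difference) without dox (open circles) and with dox (orange), in arbitrary units on a log axis, with 1 array per condition. Meis1, Bcl11a, Elf1 and Mecom were 2-fold or more higher with dox, and Nfe2, Etv2, Gfi1b, Hoxa9 and Myb 2-fold or more lower.

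Erythroid genes were lower with dox as a list, chiefly the globins and Car2. The embryonic beta-type globin Hbb-bh1 had a signal of 3282 without dox and 535 with dox, 5.99-fold lower, and its other probe sets were lower too, by log2 differences of -2.56 and -3.67. The embryonic alpha-type globin Hba-x was 2.01-fold lower (140 to 62.0) and the alpha globin Hba-a1 1.67-fold lower (2613 to 1559). Globin genes resemble one another, and their probe sets can cross-hybridise. Of 9 measured members 2, Hbb-bh1 and Hba-x, were 2-fold or more lower and none was 2-fold higher. The list median was -0.58, and 2 of the 10000 random lists had a median as low. It was -0.38 with a filter on both arrays or without probe sets that can cross-hybridise, still below its range. Without the signal filter it was -0.03 and no longer stood apart.

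Among 15 measured progenitor, megakaryocyte and myeloid genes, 4 were 2-fold or more lower and 1 was higher. The lower genes were Alox5ap, a protein of leukotriene synthesis (1706 to 501, 3.33-fold), Mpo, the peroxidase of myeloid granules (749 to 261, 2.76-fold), Kit, the stem cell factor receptor (3242 to 1317, 2.44-fold), and Laptm5, a lysosomal protein of blood cells (4039 to 1715, 2.34-fold). Plek, a platelet protein, was 2.43-fold higher (103 to 274). Laptm5 and Plek were named after their values were seen. The list median of -0.20 lay just below the central 95% of its random lists (-0.20 to 0.35). It ran from -0.71 with the filter at the 75th percentile to 0.0080 without one and lay inside its range under 6 of the 9 alternatives, so no shift of this list as a whole is claimed.

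Endothelial identity genes were measured in full, all 30 past the filter, and as a list were close to even. The median log2 difference was -0.044, inside the central 95% of random lists (-0.09 to 0.15). Within the list 5 genes were 2-fold or more higher, 2 were lower and 23 lay within 2-fold, while random lists held 1.35 genes past 2-fold on average. Clec14a, an endothelial lectin, was 15.6-fold higher (142 to 2445), and its 2 probe sets gave log2 differences of 3.55 and 3.96. Plvap, a protein of endothelial fenestrae (1836 to 5632), was 3.05-fold higher, and the gene for von Willebrand factor, Vwf (295 to 859), was 2.82-fold higher. The other higher genes, Robo4 and Eng, were 2.65-fold and 2.40-fold higher, and Cldn5 and Cd34 were 2.63-fold and 2.45-fold lower, all of them named after their values were seen.

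Genes of endothelial subtypes were higher with dox in part. Of 19 arterial and Notch pathway genes 5 were 2-fold or more higher and none was 2-fold or more lower. By any amount 12 were higher and 7 lower. Among the lower ones were Hey1 (-0.83), Nrarp (-0.73) and Hey2 (-0.37), named after their values were seen. Another probe set of Nrarp gave -1.53. The chemokine Cxcl12 had signals of 142 and 2388 (15.2-fold higher). The arterial ligand Efnb2 was 2.60-fold higher and the Notch ligand Jag1 2.37-fold higher, and Hes1 and Nrp1 were named after their values were seen (log2 differences of 1.18 and 1.07). The probe sets of Nrp1 ranged from -0.18 to 1.54. Of 11 venous and lymphatic genes 4 were 2-fold or more higher and none lower. They included Ccbe1 (24.1 to 1036, 26.2-fold) and the lymphatic growth factor Vegfc (624 to 1935, 3.05-fold). Lyve1, a lymphatic hyaluronan receptor, was 9.56-fold higher by its brightest probe set (37.0 to 491) but had a log2 difference of -0.95 by another. Stab1, named after its value was seen, was the other (1.21). Of 11 endocardial and flow-linked genes 6 were 2-fold or more higher and none lower. Npr3, a natriuretic peptide receptor of endocardium, was 8.67-fold higher (33.7 to 415), the endothelin precursor Edn1 3.35-fold and the flow-responsive factor Klf2 3.04-fold. The medians were 0.25 for the arterial list (range of random lists -0.15 to 0.23), 0.39 for the venous list (-0.21 to 0.31) and 1.23 for the endocardial list (-0.21 to 0.31). The rank intervals of the arterial median (-0.09 to 1.07) and the venous median (-0.47 to 3.26) held no difference. The endocardial median was smaller under other filters, 0.49 without one and 0.73 at the 75th percentile or on both arrays, and stayed above its range. A filter at the 75th percentile brought the arterial and venous lists inside their ranges, as did removal of probe sets that can cross-hybridise for the arterial list and a filter on both arrays for the venous list. Genes of smooth muscle and mesenchyme were also higher in the same sample, with a median of 2.11.

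Cardiac transcription factors were higher as a list, with 8 of 17 measured members 2-fold or more higher and 2 lower. Tbx20, a T-box factor of heart and endocardium, had a signal of 426 without dox and 9593 with dox (21.7-fold), and its 3 probe sets gave log2 differences from 3.16 to 4.44. Gata4, a zinc finger factor of the early heart, was 12.3-fold higher (112 to 1558), or a log2 difference of 1.39 by another probe set. Myocd, a coactivator of cardiac and smooth muscle genes, had signals of 1.94 and 251. The lower members were Isl1 (1562 to 581), a factor of the second heart field, and Foxh1 (2517 to 1092), a Nodal pathway factor, both named after their values were seen. The 3 probe sets of Foxh1 disagreed, from -1.19 to 0.35. The list median was 0.99, above all 10000 random lists (central 95% -0.18 to 0.32), in the sample where the smooth muscle and mesenchyme median was 2.11. The rank interval of the cardiac median ran from 0.06 to 2.96. Of the 17 genes 4 passed the filter only through the dox array. With the filter at the 75th percentile or on both arrays the cardiac median was 0.72, still above the range of its random lists.

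Cardiomyocyte structural genes and genes of smooth muscle and mesenchyme, markers of cells that the Flk1+Tie2+ gate was not meant to select, were also higher. Of 11 measured cardiomyocyte genes 7 were 2-fold or more higher and none was lower. Nebl, a protein of the Z-disc, had signals of 1, the floor of the table, and 379, and its other probe set gave a log2 difference of 1.62. The myosin light chain Myl4 was 14.7-fold higher (31.0 to 674), and the cardiac troponin T gene Tnnt2 10.8-fold higher (122 to 1469). A further 13 of the 24 listed genes did not reach the signal filter on either array. Of 16 smooth muscle and mesenchyme genes 10 were 2-fold or more higher and 2, Mylk and Smtn, were lower, Mylk by a log2 difference of -2.01 and Smtn by -1.10. The 3 probe sets of Mylk disagreed, from -2.01 to 0.74. Beside Tagln (96.7 to 3960.5), the fibrillar collagen Col3a1 (530 to 10557) was 19.4-fold higher, with a log2 difference of 4.72 by its other probe set, and the matrix proteoglycan Lum (26.8 to 1029) was 24.4-fold higher. The medians were 2.06 for cardiomyocyte genes and 2.11 for smooth muscle and mesenchyme genes, each above all 10000 random lists. The size of these medians depended on the filter, since 5 of the 11 cardiomyocyte genes and 4 of the 16 others passed it only through the dox array. Without the filter the gene list shift of cardiomyocyte structural genes was 0.35 and that of smooth muscle and mesenchyme genes 0.88, and with a filter on both arrays they were 1.08 and 0.77. Both lists stayed above the central 95% of their random lists under every alternative that gave a value.

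Regulators and markers of epithelial-mesenchymal transition included 3 of 10 that were 2-fold or more higher and none lower. These were Twist2 (163 to 1741, 9.80-fold), Snai1 (70.8 to 554, 6.57-fold) and Snai2 (977 to 5188, 5.24-fold), transcription factors that repress epithelial genes. By their brightest probe sets Vim (0.03), Fn1 (-0.08) and Cdh2 (-0.68) were not raised to that extent. The list median of 0.61 lay above its range of -0.19 to 0.28 but was 0.03 without the signal filter. That setting added the epithelial genes Cdh1 (-0.66), Epcam (-0.46) and Esrp1 (-1.60), dim on both arrays. The list mixes epithelial and mesenchymal genes, so its median does not measure a transition. The mesenchyme list was higher in the same sample, at a median of 2.11.

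Signalling genes were higher in the BMP and TGF-beta list, where 7 of 14 were 2-fold or more higher and none lower. Tgfbi had signals of 230 and 7760, Bmper, a secreted modulator of BMP, was 11.03-fold higher (208 to 2453), and the ligand Bmp4 was 4.63-fold higher (720 to 3398). The median was 1.05, above all 10000 random lists. Of 11 Wnt pathway genes 5 were 2-fold or more higher and 1, Rspo3, was lower (4904 to 2403). Sfrp1, a secreted Wnt antagonist, was 20.3-fold higher (90.7 to 2148), although the log2 differences of its 4 probe sets ranged from 0.29 to 4.34. The ligand Wnt2 was 7.65-fold higher (40.1 to 413) and the receptor Fzd4 4.11-fold higher (398 to 1683). Dkk1 and Znrf3, named after their values were seen, had log2 differences of 1.34 and 1.09. By any amount 8 of the 11 were higher and 3 lower. The lower ones besides Rspo3 were Axin2 (-0.82) and Lef1 (-0.50), both named after their values were seen. The list holds antagonists such as Sfrp1 beside ligands, so its median does not measure Wnt activity. The Wnt list median was 0.91, above all 10000 random lists, with a rank interval from -0.82 to 2.94. It was 0.49 with the mean of probe sets and 0.51 with a filter on both arrays, still above its random lists' range. The smooth muscle and mesenchyme list, with a median of 2.11, was higher in the same sample as both of these lists.

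Cell cycle genes were lower by a small amount. Of 24 measured genes 23 had a lower signal with dox, yet all 24 lay within 2-fold by their brightest probe sets. Other probe sets went as low as -1.11 for Rrm2 and -1.05 for Mcm7, and as high as 0.13 for Mcm3 and 0.04 for Top2a. In the same sample the smooth muscle and mesenchyme list had a median of 2.11. The mitotic kinases Aurkb (2648 to 1545) and Plk1 (3453 to 2031) had log2 differences of -0.77 and -0.76, and Tyms, the thymidylate synthase (131 to 74.8), had -0.70. The median was -0.42, below all 10000 random lists (-0.10 to 0.13), and it stayed between -0.52 and -0.40 under all 9 alternatives.

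**Figure D3:**
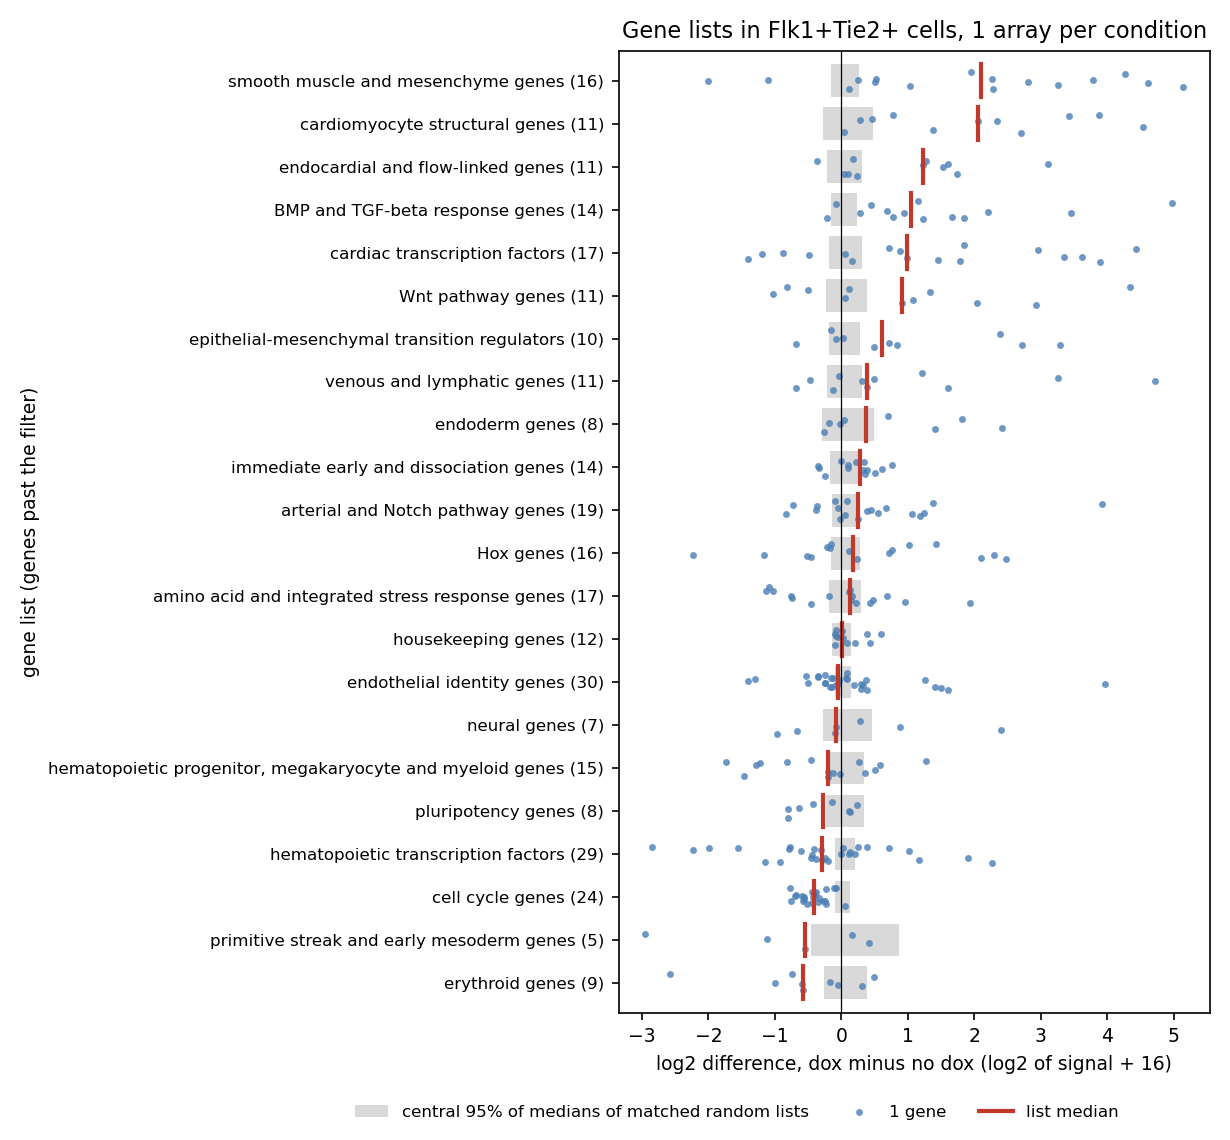
Log2 difference (dox minus no dox, of signal + 16) of each gene past the filter (points), by gene list with the number of genes in brackets, with the list median (red line) and the central 95% of medians of 10000 random lists matched on signal (grey band), with 1 array per condition. The smooth muscle and mesenchyme list has the highest median, 2.11, and the erythroid list the lowest, -0.58.

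Genes of earlier stages and other germ layers were mostly dim. Of 5 measured primitive streak genes Cdx2 and Evx1 (166 to 67.8) were 2-fold or more lower, and Eomes had a log2 difference of -0.55. The list median was -0.55 (random lists -0.45 to 0.87). All 8 measured pluripotency genes lay within 2-fold, with a median of -0.28 (-0.23 to 0.35). Lin28a had a log2 difference of -0.81, Utf1 -0.80 and Dppa4 -0.64. The rank intervals of the streak median (-2.95 to 0.42) and the pluripotency median (-0.81 to 0.24) held no difference. Neither list stood apart from random lists without the signal filter, nor did the pluripotency list with the mean of probe sets. Of 8 endoderm genes the 3 that were 2-fold or more higher were keratins of simple epithelia, which mesothelium also carries. Krt8 was 5.35-fold higher (1095 to 5934), Krt18 3.53-fold (969 to 3467) and Krt19 2.66-fold (105 to 305). The endoderm median was 0.37 (-0.29 to 0.50), inside its range, and moved with the processing. It was -0.055 without the signal filter and 0.039 with a filter on both arrays, both inside their ranges, and 0.71, above its range, without probe sets that can cross-hybridise. Of 7 neural genes 1, the fatty acid binding protein Fabp7, was higher (96.9 to 584). The others lay within 2-fold by their brightest probe sets, among them Nes at -0.97 and Ncam1 at 0.88 with probe sets in both directions. Another probe set of Nes was past 2-fold, at -1.62 (1073 to 339). The neural median was -0.08 (-0.27 to 0.46). Only 4 paraxial mesoderm and skeletal muscle regulators passed the filter. Of these Tcf15 was 2.02-fold lower (1085 to 528), while Eya1 and Dll3 had log2 differences of 0.39 and 0.12.

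Hox genes went both ways, with 5 of 16 measured genes 2-fold or more higher and 2 lower, and a median of 0.18 (-0.16 to 0.29) that was slightly negative under 3 alternatives. Hoxa2 (26.4 to 221) was 5.60-fold higher and Hoxa3 (94.4 to 525) 4.90-fold higher, and the lower genes were Hoxa9 and Hoxb6 (2195 to 977). Hoxb6 was named after its value was seen, as were the other higher genes Hoxa5 (2.10), Hoxb1 (1.42) and Hoxc6 (1.03). Other probe sets of Hoxa5 and Hoxc6 gave -0.06 and -0.23. Amino acid and integrated stress response genes had a median of 0.14 (-0.18 to 0.30), or -0.18 with the filter at the 75th percentile. By their brightest probe sets 1 of 17 was 2-fold or more higher and 3 were lower. Cebpb was 3.81-fold higher (69.3 to 309), and the lower genes were Chac1 (194 to 79.7), Shmt2 (2110 to 983) and, named after its value was seen, Psat1 (5490 to 2681). Shmt2 and Psat1 encode enzymes of glycine and serine synthesis. A probe set of Shmt2 that is not prone to cross-hybridisation gave -0.29, and another of Psat1 gave -1.84. Named after their values were seen, Phgdh and Mthfd2 had probe sets on both sides of the 2-fold limit. Those of Phgdh ranged from -1.91 to -0.45 and those of Mthfd2 from -1.41 to -0.74. All 14 immediate early and dissociation genes lay within 2-fold by their brightest probe sets, with a median of 0.28 (-0.16 to 0.25). The largest of these differences were 0.76 for Hspa1b, 0.61 for Btg2 and 0.50 for Dusp1. Another probe set of Btg2 was past 2-fold, at 1.28 (319 to 799). With the filter at the 75th percentile this list no longer stood apart. The rank interval of its main median, -0.24 to 0.50, held no difference.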

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

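All 192 recomputed list medians stayed within the rank interval of the main median, but these intervals are wide, and 8 medians changed sign or reached 0. Lists left with fewer than 5 genes gave no value. Of the 8, 2 belonged to lists that had stood apart from random lists. Without the signal filter, the progenitor, megakaryocyte and myeloid median was 0.0080 and the primitive streak median 0, where both had been negative. The other 6 belonged to lists inside their random range. The endoderm median was -0.055 without the filter and the amino acid median -0.18 with the filter at the 75th percentile. The Hox median was -0.025 with that filter and -0.016 with a filter on both arrays or the mean of probe sets, and the housekeeping median -0.037 without probe sets that can cross-hybridise. The cause was not tested. The filter set the counts most. Without it 372 genes were 2-fold or more lower. At the 75th percentile 350 were higher and 135 lower, and with a filter on both arrays 417 were higher. These settings test other numbers of genes (18193, 7395 and 10920). The other 2-fold counts stayed within 1.5 times, and Mesp1 within the probe set SD. The larger folds moved more. At 4-fold, 237 higher and 25 lower genes became 126 and 12 at the 75th percentile, 110 and 7 with a filter on both arrays, and 158 and 14 with a pseudocount of 64. At 8-fold, 88 and 3 became 51 and 1, 26 and 0, and 43 and 1 in these settings. The 8-fold lower count was 7 with quantile normalization, 5 with loess centring, 10 with a pseudocount of 1 and 1 with the mean of probe sets. Across all alternatives the median of the hematopoietic transcription factors ran from -0.34 to -0.24, and it stayed below the central 95% of its random lists in 9 of 9. Of 750 recomputed values of named genes, 65 moved by more than the probe set SD of 0.38 log2 units, and none of those past 2-fold changed sign. By construction, the pseudocounts moved dim genes most: the log2 difference of Shisa3 was 8.94 with a pseudocount of 1 and 4.86 with 64. Quantile normalization moved the median of all genes by -0.07. No paired analysis was possible because each condition had 1 array, and no replicate could be left out for the same reason. Signal over background is unknown here, so dim values carry the largest uncertainty.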

Other observations

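The tests of non-endothelial cells, of the globins and of the Hox groups were chosen after the results they bear on had been seen. The predictions for the others were written before their values were looked at. Several genes with high differences, noticed after the values were seen, are textbook markers of epicardium and mesothelium, the linings of the heart and the body cavities. Wt1 had a signal of 35.9 without dox and 1118 with dox, Upk3b 15.8 and 475, and Bnc1 89.5 and 1422. A further list of 17 such genes, none of which had been looked at, was then tested, and 7 passed the signal filter. Rspo1 (12.1 to 208), Tcf21 (67.1 to 523), Lrrn4 (152 to 423) and Upk1b (40.6 to 132) were 2-fold or more higher, while Gpm6a (397 to 154) was lower. A second probe set of Tcf21 gave a log2 difference of -0.53 against 2.70. The median was 1.38, above the central 95% of random lists (-0.33 to 0.57). Without the signal filter, 16 genes had a median of -0.01 that did not stand apart, and of the 4 genes past a filter on both arrays the median was -0.50. An epicardial or mesothelial programme in the dox sample may account for part of the list, but these 2 arrays do not decide it.

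Hox genes of paralogue groups 1 to 5 had a median log2 difference of 0.75 over 10 genes (random lists -0.22 to 0.37), and those of groups 6 to 10 a median of -0.37 over 6 genes (-0.29 to 0.42). The medians differed by 1.11. The split into these groups was made after the Hox values had been seen, so the medians restate them and do not test a shift from posterior to anterior Hox genes, which stays open. The median of groups 1 to 5 was 0.48 with the filter at the 75th percentile, where it lay at the 96.8th percentile of its random lists, and with a filter on both arrays, and Hoxa2 and Hoxa3 passed the filter only through the dox array. That of groups 6 to 10 was -0.83 over 4 genes at the 75th percentile and -0.22 over 11 genes without a filter. Probe sets disagreed on both sides. The other probe set gave -0.06 for Hoxa5 (against 2.10), -1.16 for Hoxb3 (against 0.77) and -0.02 for Hoxa9 (against -2.23). With Hoxa9 and Hoxb6 as the only genes of groups 6 to 10 that were 2-fold lower, and Hoxc6 2-fold higher (136 to 292), the posterior side rests on few genes. Another probe set of Hoxc6 gave -0.23.

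More genes were 2-fold higher than lower with dox (671 against 243). A difference in signal scale between the arrays did not account for all of this. The share of higher genes was still 64.8% (Wilson 95% interval 61.6 to 67.8) after quantile normalization. Scale may account for part of it, since the share had been 73.4% (70.5 to 76.2) and the counts became 589 and 320. For noise of dim signals, the share was 72.2% (68.0 to 76.0) with the filter at the 75th percentile. That filter keeps genes that are dim on 1 array. With the filter on both arrays, at their medians, the share was 71.3% (67.5 to 74.8). Noise of signals below these medians therefore did not account for all of the excess either. Each of these shares could have been 50%. A difference between these cultures that is unrelated to Mesp1, an effect of dox itself and the induction of Mesp1 remain open, because the design holds 1 culture of each kind and no dox control without the transgene.

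Smooth muscle and mesenchyme genes were higher with dox. The median was 2.11, and its size depended on the filter, at 0.88 without one and 0.77 with a filter on both arrays. Without probe sets that can cross-hybridise the median was 1.95 against random lists from -0.20 to 0.31. Among the measured genes only Acta2 and Cald1 were represented by such probe sets. Their removal could hardly have brought the median into that range, so it does not decide whether cross-hybridisation contributes. Non-endothelial cells in the sorted dox sample would lower endothelial genes together, and their median was -0.044, with a rank interval from -0.18 to 0.29. That interval holds both no loss and a small loss, so cells of another type and expression by endothelial cells cannot be told apart here. The sort for Flk1 and Tie2 was meant to remove such cells. Without dox, 12 of the 16 genes had signals at or above the array's median. The other 4, Tagln, Cnn1, Col1a1 and Lum, were all 2-fold or more higher with dox. These signals do not tell which cells carried the higher expression.

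Erythroid genes were lower with dox (median -0.58, or -0.03 without the signal filter). The uniform loss of one erythroid population would lower every globin by 1 ratio. The test used the globins only. Of the other members Car2 (-0.60), Cited4 (-0.17) and Slc25a37 (-0.04) were lower and Epor (0.31) and Sptb (0.49) higher. The log2 differences of Hbb-bh1, Hba-x, Hba-a1 and Hbb-y spanned 2.00, against a 95% limit of 1.37 for the span of 4 values from the probe set SD. Without Hbb-bh1 the other 3 spanned 0.42, against a limit of 1.25, so the excess rests on 1 gene, whose own probe sets spanned 1.11. A uniform loss therefore stays open, as do a change in the stage of the erythroid cells and a loss in some populations and not in others, which were not tested. The hematopoietic transcription factors were lower as a list in the same sample (median -0.29, rank interval from -0.60 to 0.13). Whether fewer blood cells or lower expression per cell accounts for that was not tested.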
